A study of Mus musculus with 32 samples.

How the data were processed

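RNA was extracted with Trizol and an RNeasy Plus kit, and libraries were prepared at BGI by protocols not described further. The authors deposited expected counts as estimated reads per gene without normalisation, in the columns of RSEM gene results. The authors computed deposited FPKM from expected count, deposited length (mean transcript length of a gene in bases) and reads assigned to genes per library. The submitters' processing notes name Bowtie2, HISAT, RSEM and the build mm10, without the role or version of each. Genes with an FPKM under 0.01 were not listed and were set to 0. Of the expected counts, 78.8% to 80.6% per library were whole numbers (tolerance 0). No mitochondrially encoded gene was listed. Genes carry Entrez identifiers, and of 20612 listed in any library 20551 matched the RefSeq annotation of GRCm38.p6 directly, 9 by transcript and 52 not at all. They included 18179 protein-coding genes and 1675 long noncoding RNAs.

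Rounded expected counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept at 1 CPM (counts scaled to library size) or more in at least 4 libraries, which left 15632 genes, or 15084 for the comparison of branches. Library sizes were scaled by TMM factors of 0.923 to 1.143, and log2 values used a prior count of 1. Treatments were compared over stages in a quasi-likelihood model with a term for stage and a term for treatment (21 residual degrees of freedom). Single stages used a model of stage by class, with the 3 bisphenols as 1 class (16 residual degrees of freedom), in which the lone DMSO library was assumed to vary like the others. The comparison of branches used an interaction term over the 24 libraries of the 6 later stages. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and in comparisons of stages also at an absolute log2 change of 1 or more. The SE of a log2 change was derived from the test's F value, and intervals are at 95% confidence.

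The comparisons, thresholds, alternatives and 37 gene lists (926 genes for cell types, pathways and receptors) were fixed before the data were examined, except alternatives named as chosen afterwards. Lists with at least 5 members among the genes tested were compared with the other genes by camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation. Named genes followed a rule fixed at the same time. For stages they were the 6 highest and 6 lowest log2 changes among called genes with a mean of 10 FPKM or more and the same direction in all 4 treatments. For treatments over stages and for branches they were the 10 higher and 10 lower called genes with the smallest p and 1 FPKM or more, and for single stages the 5 and 5 with the largest change and 5 FPKM or more. Where fewer than 5 were called, the 5 with the smallest p were named as not past the threshold. From each list described, members with the largest change among called members were named, or those with the smallest p. Gene models and pseudogenes were passed over. A few genes chosen by these rules are not reported here. Other tools were DESeq2 1.42.0 and limma with trend on log2(FPKM + 1). Correlations between compounds were compared with 20 simulations without effects. In simulated data of the same size, 93% of genes changed by a log2 of 1 were recovered over stages, 69% at EB day 12, 63% in ESCs and 37% between EB days 6 and 9, where the estimate itself had to reach 1. Per comparison simulated, 2 to 17 unchanged genes were called.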

Results

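RNA was measured by sequencing in J1 mouse embryonic stem cells (ESCs, a line from strain 129S4/SvJae) and in cells differentiated from them. Cultures received 100 nM bisphenol A (BPA), bisphenol F (BPF) or bisphenol S (BPS), or the solvent dimethyl sulfoxide (DMSO) alone. In BPA a carbon carrying methyl groups joins the phenol rings, in BPF a methylene group does so and in BPS a sulfonyl group. The 32 libraries formed 8 stages with 4 treatments, 1 library for each combination: ESCs at day 0, embryoid bodies (EBs, floating aggregates of differentiating cells) at days 4, 6, 9, 12 and 20, EBs at day 8 after 4 days in retinoic acid (RA EBs), and neural progenitor cultures (NPCs) at day 10. EBs of days 6 to 20 made up the global branch, RA EBs and NPCs the neural branch. Total expected counts per library ran from 9574833 to 11070149, and 16326 to 17839 genes were listed per library. No treatment was repeated within a stage, so stages were compared over their 4 libraries and treatments over the 8 stages. The p-values measure the spread between these samples, since the labels give no replicates. Unless a group is named, levels are mean FPKM ± SD of a stage's 4 libraries, log2 changes are edgeR estimates ± SE, and adjusted p for genes is from the edgeR quasi-likelihood test. For gene lists fixed before the data were examined, the camera adjusted p uses a preset correlation between genes. Members at their bound are those without counts in one group, set to the change that a floor of 3 counts over the group allows. Such floors cover counting error only, and not how estimated reads were divided between similar genes.

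ESCs and EBs of day 4 were compared to find what changed when stem cells were aggregated. Fgf5, a growth factor of the primed epiblast (Entrez 14176, GRCm38 chromosome 5, 98254184 to 98277033), went from 0.0675 ± 0.0472 to 54.1 ± 5.52 FPKM (log2 change 9.66 ± 0.37, adjusted p = 3.1e-18). Car4, a carbonic anhydrase, rose by 9.47 ± 0.34 to 354 ± 30.5 FPKM, cardiac actin Actc1 by 10.01 ± 1.07 and the guanylate-binding protein gene Gbp2 by 9.78 ± 0.44. Gbp2b went from 0.0075 ± 0.015 to 27.6 ± 2.95 FPKM and Psmb8, an immunoproteasome subunit, from 0.02 ± 0.04 to 17.6 ± 1.88. The lowest changes were those of A2m (-6.78 ± 0.22), the keratin Krt42 (-6.75 ± 0.36), Mras (-5.98 ± 0.15), Crxos (-5.95 ± 0.29), Tbx3 (-5.78 ± 0.24) and the water channel Aqp3 (-5.76 ± 0.27). With 4376 genes past the threshold, 2249 were higher and 2127 lower at day 4.

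Naive pluripotency genes fell together: 23 of 30 were lower and 2 higher (23 and 2 adjusted over the list alone), with a median log2 change of -2.79 (camera adjusted p = 3e-09, and adjusted p = 0.012 with an estimated correlation). Among them, Klf4 changed by -5.40 ± 0.22, Tfcp2l1 by -5.08 ± 0.13 and Prdm14 by -4.62 ± 0.20, all transcription regulators of the naive state. Of 19 formative and primed epiblast genes 12 rose and 1 fell (12 and 2 adjusted over the list alone), including Sox3 (5.72 ± 0.31), the DNA methyltransferase Dnmt3b (5.06 ± 0.15) and the tight-junction gene Cldn6 (5.01 ± 0.42). Their median was 2.06 (camera adjusted p = 0.00036, adjusted p = 0.11 with an estimated correlation). Smooth muscle genes rose in 12 of 16 (12 adjusted over the list alone). Contractile genes included Acta2 at 141 ± 10.1 FPKM (8.24 ± 0.94), Cnn1 at 48.1 ± 1.82, Tagln at 279 ± 12.1 and Myl9 at 62.3 ± 4.34. Their median was 2.60 (camera adjusted p = 0.0012, adjusted p = 0.84 with an estimated correlation).

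Cholesterol synthesis genes fell in 12 of 25 and rose in 1 (12 and 1 adjusted over the list alone). Msmo1 was at -1.84 ± 0.08, Insig1 at -1.78 ± 0.08, Pmvk at -1.68 ± 0.08 and Cyp51 at -1.40 ± 0.08. The list's median was -0.92 (camera adjusted p = 3e-09, adjusted p = 0.49 with an estimated correlation). Genes of the unfolded protein and integrated stress response fell in 10 of 25 (10 adjusted over the list alone, median -0.40, camera adjusted p = 0.0012, adjusted p = 0.53 with an estimated correlation). Chac1 changed by -4.22 ± 0.29, Trib3 by -3.12 ± 0.19, Ddit3 by -3.08 ± 0.16 and asparagine synthetase Asns by -2.24 ± 0.13. Hox genes, which pattern the body axis, fell in 16 of 29 (16 adjusted over the list alone, median -2.67, the same with 5 members at their bound). The camera adjusted p was 0.0027, and the adjusted p = 0.69 with an estimated correlation. Their levels were low: Hoxc10 was at 1.74 ± 0.384, Hoxd9 at 0.89 ± 0.254 and Hoxb13 at 1.47 ± 0.305 FPKM in ESCs, and Hoxc12, without counts at day 4, was at least 17.4-fold lower there. With limma on log2(FPKM + 1) 2385 genes passed (1129 higher and 1256 lower), and DESeq2 did not call Hoxc12.

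EB day 6 was compared with EB day 4, the span in which germ layer genes came on. Cer1, a secreted inhibitor of nodal signalling (Entrez 12622, chromosome 4, 82881751 to 82885151), went from 0.0175 ± 0.0287 to 71.6 ± 46.4 FPKM (adjusted p = 2.2e-16). The morphogen gene Shh went from 0.01 ± 0.02 to 16.9 ± 8.34 FPKM, Wnt1 from 0.03 ± 0.06 to 25 ± 10.7 and Irx1 from 0.0125 ± 0.025 to 13.3 ± 5.4. Samd3, without counts at day 4, was at least 420-fold higher, and Mab21l2 rose by 8.75 ± 0.49. The lowest changes were those of the pluripotency gene Utf1 (-3.52 ± 0.15), Cbr3 (-3.52 ± 0.18), the troponin gene Tnnt1 (-3.52 ± 0.28), Thy1 (-3.49 ± 0.18), Rgl3 (-3.45 ± 0.19) and the noncoding RNA Platr10 (-3.38 ± 0.19). Of 3050 genes past the threshold 1682 were higher and 1368 lower.

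Primitive streak genes rose in 13 of 16 and fell in 1 (13 and 1 adjusted over the list alone, median 3.38). Brachyury, T, was at 43.2 ± 22.7 FPKM (8.33 ± 0.40), Foxa2 at 35.2 ± 15.4 (6.84 ± 0.38) and Wnt3a at 2.46 ± 0.356. The camera adjusted p was 2e-05, and 0.022 with an estimated correlation. Neural progenitor genes rose in 26 of 38 and fell in 2 (26 and 2 adjusted over the list alone, median 3.35, camera adjusted p = 4.6e-10, and 0.032 with an estimated correlation). Nkx6-1 changed by 7.53 ± 0.41 and En1 by 6.99 ± 0.43, Pax3 went from 0.015 ± 0.03 to 4.75 ± 1.16 FPKM, and Hes3, without counts at day 4, was at least 22.6-fold higher. Wnt, BMP and Notch genes rose in 30 of 41 (30 adjusted over the list alone, median 2.05, camera adjusted p = 1.8e-12, and 0.0027 with an estimated correlation). Dkk1 was at 8.21 ± 0.45 and Rspo3 at 6.98 ± 0.61.

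Imprinted genes rose in 16 of 26 and fell in 3 (16 and 3 adjusted over the list alone, median 1.88, camera adjusted p = 2.2e-05, and 0.029 with an estimated correlation): Plagl1 by 4.80 ± 0.20, Dlk1 by 4.69 ± 0.45, the growth factor Igf2 by 3.56 ± 0.36 to 194 ± 22.4 FPKM, and Nnat by 3.17 ± 0.16. In limma on log2(FPKM + 1) 1272 genes passed, and Hes3 was not called.

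EB day 9 was compared with EB day 6, the span in which neuronal genes came on. Pax1, of the sclerotome, went from 0.06 ± 0.101 to 11.5 ± 9.84 FPKM (log2 change 7.19 ± 0.77, adjusted p = 1.3e-08), and Vgll2 (6.11 ± 0.73), Sim2 (5.80 ± 0.20) and Stmn4 (5.42 ± 0.36) rose too. Pax1 and Vgll2 rose mainly with bisphenols. The fibroblast matrix genes Col3a1 and Lum rose by 5.43 ± 0.75 and 5.39 ± 0.63. Cer1 fell from 71.6 ± 46.4 to 0.835 ± 0.69 FPKM (-6.47 ± 0.27), Fgf5 by -4.61 ± 0.25, Gbp2 by -4.60 ± 0.28, Gbp2b by -4.50 ± 0.27, Eras by -4.36 ± 0.32 and Psmb8 by -4.35 ± 0.27. Of 2300 genes past the threshold 1679 were higher and 621 lower.

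Neuronal genes rose in 33 of 46 and fell in 2 (33 and 2 adjusted over the list alone, median 2.18, or 2.14 with 2 members at their bound). Their camera adjusted p was 7.3e-16, and 0.028 with an estimated correlation. Doublecortin, Dcx, changed by 6.64 ± 0.27, Slc17a6 by 5.93 ± 0.45 and Nhlh2 by 5.73 ± 0.35. Endothelial genes rose in 15 of 20 (15 adjusted over the list alone, median 1.96, camera adjusted p = 0.0071, adjusted p = 0.75 with an estimated correlation). Tie1 changed by 4.48 ± 0.81 and the cadherin Cdh5 by 4.28 ± 0.64, and Emcn and Icam2 reached 3.18 ± 2.61 and 1.63 ± 1.56 FPKM. Cardiac genes rose in 16 of 26 (16 adjusted over the list alone, median 1.43, camera adjusted p = 0.024, adjusted p = 0.82 with an estimated correlation). Tnnt2 was at 11 ± 11.5 FPKM (3.22 ± 0.81). Ttn (4.94 ± 1.18), Mybpc3 (3.39 ± 0.85) and Pln, at least 5.83-fold higher from no counts at day 6, rose in 3 of 4 treatments. Bisphenols exceeded DMSO at EB day 9 by medians of 2.12 for the cardiac and 2.40 for the endothelial list, so much of both rises lay in the bisphenol libraries. By limma on log2(FPKM + 1) 916 genes passed and Mybpc3 was not called. Mybpc3 lost its call without BPS, Tnnt2 without BPS or BPF.

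EB day 12 was compared with EB day 9. The neuronal regulators Bcl11a (3.93 ± 0.19, adjusted p = 1.2e-14), Scrt2 (3.49 ± 0.19) and Scrt1 (3.38 ± 0.20) rose, as did Tal1 (3.42 ± 0.28), Tmem35a (3.5 ± 0.24) and the smooth muscle actin Actg2 (4.54 ± 0.82). At EB day 12 Actg2 was much higher in the bisphenol libraries than in DMSO. The genes with the largest falls were Vgll2 (-3.22 ± 0.53), Prtg (-3.21 ± 0.13), the RNA-binding Lin28a (-3.18 ± 0.16), thyrotropin-releasing hormone, Trh (-3.15 ± 0.34), Dkk1 (-2.90 ± 0.28) and Nr6a1 (-2.35 ± 0.14). Of 1561 genes past the threshold 1181 were higher and 380 lower. Neuronal genes rose in 34 of 46 and fell in 2 (34 and 2 adjusted over the list alone, median 1.44, camera adjusted p = 1.5e-19, and 0.015 with an estimated correlation). The GABA transporter gene Slc32a1 (Entrez 22348, chromosome 2, 158607260 to 158615747) changed by 5.13 ± 0.33, Myt1l by 3.96 ± 0.25, Lhx1 by 3.37 ± 0.44 and Gad2, an enzyme of GABA synthesis, by 2.96 ± 0.23. Of 34 cell cycle genes 0 were called in edgeR at a log2 change of 1 (0 adjusted over the list alone), though their median was -0.47 (camera adjusted p = 1.9e-13, adjusted p = 0.29 with an estimated correlation). Mcm4 was at -0.72 ± 0.06 (adjusted p = 5.2e-11), Mcm5 at -0.67 ± 0.06, Cdc6 at -0.72 ± 0.07 and Bub1 at -0.76 ± 0.07. With limma on log2(FPKM + 1) 606 genes passed, and Myt1l was not called.

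EB day 20 was compared with EB day 12, the longest step of the global branch. Gfap, an intermediate filament of astrocytes (Entrez 14580, chromosome 11, 102887336 to 102897200), went from 0.19 ± 0.116 to 316 ± 13.6 FPKM (log2 change 10.58 ± 0.19, adjusted p = 2e-22). Clec3b and Scrg1, without counts at day 12, were at least 228-fold and at least 125-fold higher. The serpin Serpina3n rose by 9.85 ± 0.21, and Ecrg4 and Serpina3m went from 0.0575 ± 0.115 and 0.03 ± 0.06 to 35.5 ± 19.7 and 13.2 ± 9 FPKM. Embryonic globins were lower: Hba-x, without counts at day 20, was at least 153-fold lower, and Hbb-bh1 was at 0.0425 ± 0.085 against 22.4 ± 31.3 FPKM. The proneural gene Neurog1 (-6.10 ± 0.31), Igdcc3 (-5.35 ± 0.24), Fndc3c1 (-4.80 ± 0.16) and Tal2 (-4.06 ± 0.20) fell. Of 4123 genes past the threshold 2751 were higher and 1372 lower. Glial genes rose in 11 of 16 (11 adjusted over the list alone, median 1.80, camera adjusted p = 0.0035, and 0.031 with an estimated correlation). The water channel Aqp4 was at 6.89 ± 0.22 and the oligodendrocyte genes Mog at 3.78 ± 0.61 and Olig1 at 2.90 ± 0.37. Cell cycle genes fell in 31 of 34 (31 adjusted over the list alone, median -1.96, camera adjusted p = 2.1e-22, adjusted p = 0.13 with an estimated correlation). Rrm2 was at -2.69 ± 0.12, Aurkb at -2.40 ± 0.10, Foxm1 at -2.22 ± 0.10 and Bub1b at -2.22 ± 0.07. Neural progenitor genes fell in 22 of 38 and rose in 2 (22 and 2 adjusted over the list alone, median -1.33, camera adjusted p = 0.00097, adjusted p = 0.77 with an estimated correlation). Hes3 was at -4.01 ± 0.41, Hes5 at -3.88 ± 0.23 and Dbx2 at 4.77 ± 0.37. In limma on log2(FPKM + 1) 2627 genes passed, and DESeq2 did not call Scrg1.

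**Figure D1:**
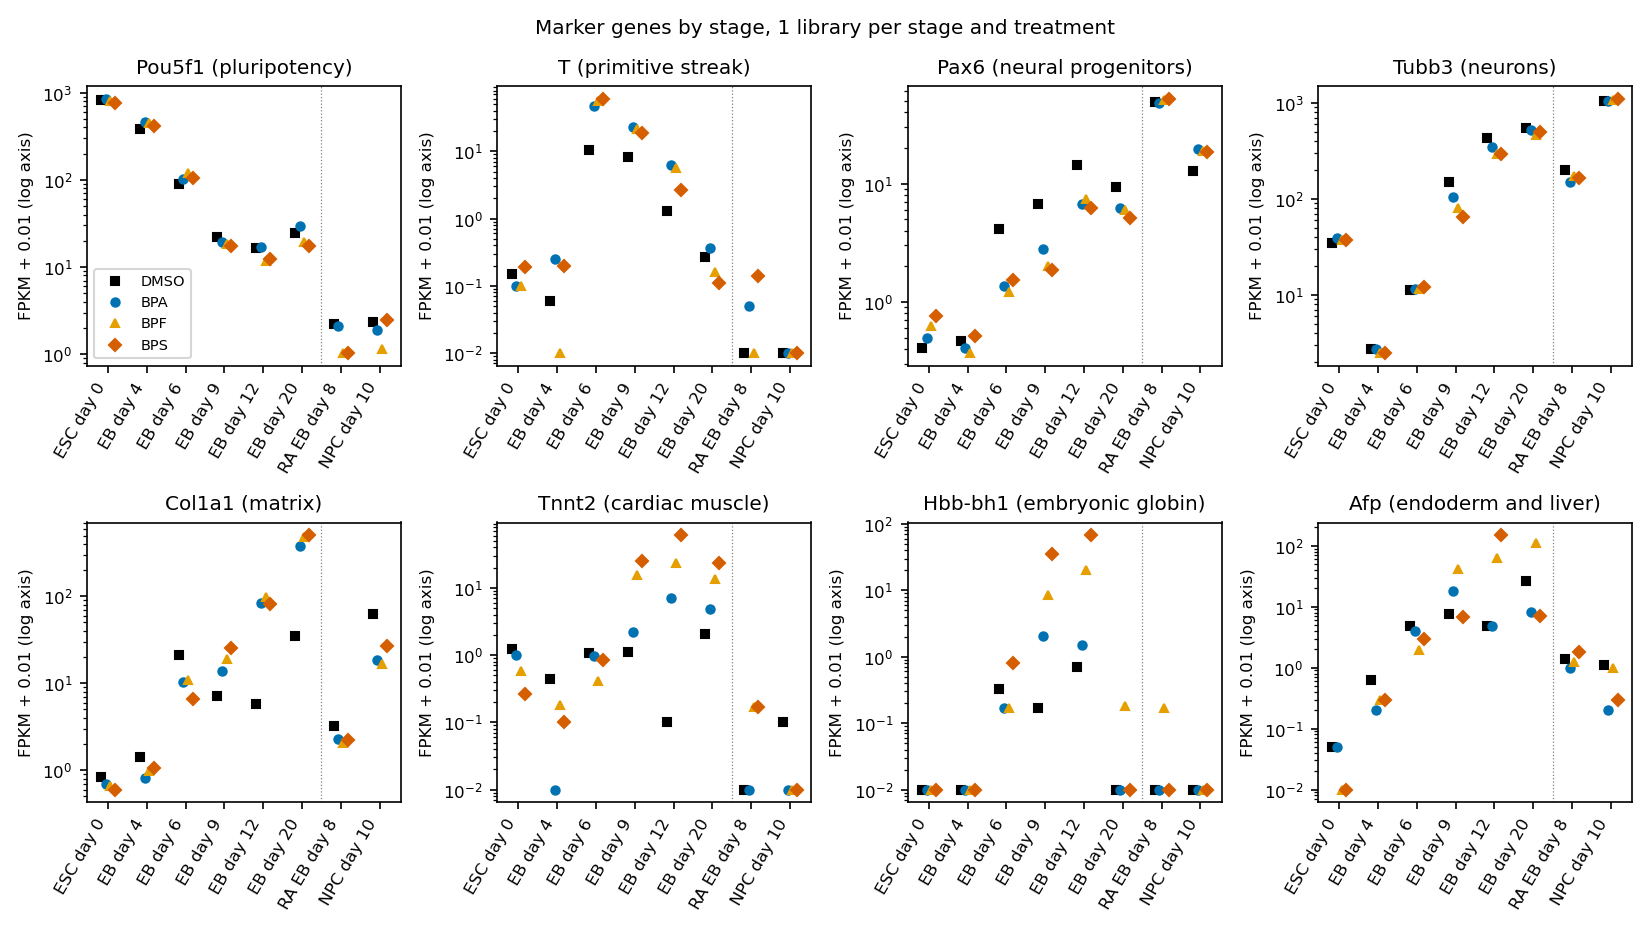
Levels of marker genes by stage in FPKM + 0.01 on a log axis, so that zeros are drawn at 0.01, with 1 point per library coloured by treatment. Pou5f1 falls in RA EBs and T peaks at EB day 6.

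RA EBs of day 8 were compared with EBs of day 4, from which they were made by 4 days in retinoic acid, a signal that turns on Hox genes and neural fates. Msx3, Arg1 and Olig3, all without counts at day 4, were at least 1020-fold, 408-fold and 374-fold higher. Hoxd4 went from 0.01 ± 0.02 to 56.0 ± 1.81 FPKM, Hoxc5 from 0.0175 ± 0.035 to 73.4 ± 4.56, and Hoxb5 rose by 11.17 ± 0.56 to 167 ± 23.7. The pluripotency regulator Pou5f1 (Entrez 18999, chromosome 17, 35506032 to 35510777) fell from 431 ± 36 to 1.58 ± 0.639 FPKM (log2 change -8.31 ± 0.19, adjusted p = 4.6e-23). Utf1 was at -9.27 ± 0.23 and Tdgf1 at -8.45 ± 0.33. Platr10 and Vrtn were at 0.0225 ± 0.045 and 0.015 ± 0.0173 against 36.2 ± 3.38 and 18.9 ± 2.55 FPKM, and Foxi3, without counts in RA EBs, was at least 271-fold lower. Of 5425 genes past the threshold 2974 were higher and 2451 lower. Retinoic acid targets rose in 27 of 27 (27 adjusted over the list alone, median 6.38, camera adjusted p = 2.6e-12, and 0.016 with an estimated correlation). They included Cyp26b1, which breaks retinoic acid down (10.99 ± 0.31), Hoxa5 (10.47 ± 0.43) and Hoxb2 (10.19 ± 0.40). Hox genes rose in 26 of 29 and fell in 1 (26 and 1 adjusted over the list alone, median 9.41, the same with 2 members at their bound, camera adjusted p = 4.4e-11, and 0.018 with an estimated correlation), with Hoxa3 going from 0.02 ± 0.04 to 45.7 ± 4.23 FPKM. Neuronal genes rose in 42 of 46 and fell in 3 (42 and 3 adjusted over the list alone, median 3.01, camera adjusted p = 8.8e-12, and 0.019 with an estimated correlation). Dcx changed by 9.26 ± 0.25 and Nhlh2 by 8.56 ± 0.29, and Neurod4 and Nhlh1 reached 15.3 ± 0.956 and 21 ± 2.57 FPKM. Neural progenitor genes rose in 28 of 38 and fell in 4 (28 and 4 adjusted over the list alone, median 4.75, camera adjusted p = 3e-08, adjusted p = 0.057 with an estimated correlation). Dbx1 was at 10.84 ± 0.50, Neurog1 at 9.59 ± 0.36, Neurog2 at 9.51 ± 0.36 and Pax3 at 14.4 ± 1.2 FPKM. Pluripotency genes fell in 24 of 30 and rose in 2 (24 and 2 adjusted over the list alone, median -4.35, camera adjusted p = 8.1e-10, and 0.0054 with an estimated correlation), Fgf4 among them (-8.05 ± 0.32). By limma on log2(FPKM + 1) 3187 genes passed.

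NPCs of day 10 were compared with RA EBs of day 8, from which they were grown. Slc17a6, the vesicular glutamate transporter (Entrez 140919, chromosome 7, 51621830 to 51671126), went from 0.01 ± 0.0115 to 12.5 ± 1.33 FPKM (adjusted p = 1.2e-17). Mab21l2 (8.46 ± 0.31), the sensory neuron factor Pou4f2 (7.88 ± 0.28), Mab21l1 (7.20 ± 0.31), the adhesion gene Chl1 (6.37 ± 0.25) and Caly (6.27 ± 0.27) rose. The retinoic acid hydroxylases Cyp26b1 (-8.19 ± 0.25) and Cyp26a1 (-6.81 ± 0.44) fell, as did Nepn (-7.05 ± 0.46), Stra8 (-7.03 ± 0.42), Olig2 (-6.50 ± 0.47) and Arg1 (-5.77 ± 0.49). Of 5543 genes past the threshold 2827 were higher and 2716 lower, a majority that turned without a filter (2910 and 2962), with a filter of 5 CPM and without the DMSO or BPA libraries. Neuronal genes rose in 40 of 46 and fell in 1 (40 and 1 adjusted over the list alone, median 2.73, camera adjusted p = 2.4e-11, adjusted p = 0.088 with an estimated correlation). Gad2 was at 4.77 ± 0.21, Pou4f1 at 4.63 ± 0.16 and Syt1 at 4.50 ± 0.17. Axon guidance genes rose in 25 of 45 and fell in 2 (25 and 2 adjusted over the list alone, median 1.10, camera adjusted p = 5.5e-05, and 0.037 with an estimated correlation), led by Dscam (5.62 ± 0.23), Epha5 (5.12 ± 0.21), Plxna4 (3.78 ± 0.14) and Ephb1 (3.77 ± 0.21). Cell cycle genes fell in 33 of 34 (33 adjusted over the list alone, median -2.23, camera adjusted p = 3e-20, adjusted p = 0.12 with an estimated correlation). Replication licensing genes included Mcm6 at -2.94 ± 0.08, Cdt1 at -2.74 ± 0.12, Mcm3 at -2.70 ± 0.08 and Cdc6 at -2.64 ± 0.08. Matrix genes rose in 26 of 43 and fell in 1 (26 and 1 adjusted over the list alone, median 1.43, camera adjusted p = 0.019, adjusted p = 0.94 with an estimated correlation). Col6a3 was at 6.87 ± 0.84, Col3a1 at 5.40 ± 0.69, Dcn at 5.31 ± 0.76 and Fbln5 at 5.01 ± 0.70. With limma on log2(FPKM + 1) 3490 genes passed.

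The branches were compared near the same age. RA EBs of day 8 were set against the mean of EBs of days 6 and 9 (n = 8 libraries). Hoxb6, without counts in those EBs, was at 143 ± 4.6 FPKM in RA EBs and at least 5370-fold higher. Hoxb8 (Entrez 15416, chromosome 11, 96279401 to 96285325) was higher by 13.54 ± 0.38 (adjusted p = 1.9e-19), Hoxc5 by 12.47 ± 0.26, Hoxb5 by 12.19 ± 0.44 and Hoxa5 by 11.19 ± 0.34, and Hoxb5os was at 142 ± 27.9 against 0.0425 ± 0.0787 FPKM. T (-9.11 ± 0.44) and Trh (-7.98 ± 0.47) were lower. Samd3 was at 0.0125 ± 0.025 against 10.7 ± 8.84 FPKM, Fgf8 at 0.0225 ± 0.045 against 13.7 ± 5.63, Cer1 at 0.0125 ± 0.025 against 36.2 ± 48.5 and the forebrain gene Otx1 at 0.025 ± 0.0332 against 10.4 ± 8.65. Of 2962 genes past the threshold 1347 were higher in RA EBs and 1615 lower. Hox genes were higher in 26 of 29 and lower in 1 (26 and 1 adjusted over the list alone, median 7.77, or 7.22 with 4 members at their bound, camera adjusted p = 1.3e-19, and 0.0031 with an estimated correlation). Retinoic acid targets were higher in 23 of 27 and lower in 2 (23 and 2 adjusted over the list alone, median 3.37, camera adjusted p = 1.9e-14, and 0.0082 with an estimated correlation). Cyp26b1 was at 8.66 ± 0.19, Hoxa3 at 8.08 ± 0.25 and Hoxb4 at 7.22 ± 0.27. Cardiac genes were lower in 16 of 26 (16 adjusted over the list alone, median -2.28, or -2.15 with 2 members at their bound, camera adjusted p = 0.0023, adjusted p = 0.77 with an estimated correlation). Myh7 was at -5.65 ± 0.63 and Tnnt2 at -5.11 ± 1.26, Csrp3 at 0.0225 ± 0.045 against 0.93 ± 0.675 FPKM, and Ttn, without counts in RA EBs, at least 50.9-fold lower. Neuronal genes were higher in 36 of 46 and lower in 2 (36 and 2 adjusted over the list alone, median 2.30, camera adjusted p = 2e-14, and 0.018 with an estimated correlation). Nhlh2 was at 5.81 ± 0.18, Myt1l at 5.63 ± 0.34, Dcx at 5.51 ± 0.15 and Lhx3 at 5.13 ± 0.39. In limma on log2(FPKM + 1) 1288 genes passed, and Myt1l and Csrp3 were not called. Ttn lost its call without the BPA, BPF or BPS libraries.

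NPCs of day 10 were set against the mean of EBs of days 9 and 12 (n = 8 libraries). Hoxb9 (11.08 ± 0.21, adjusted p = 7.9e-25), Hoxb8 (10.95 ± 0.30) and Hoxc5 (9.90 ± 0.21) were higher, Hoxb6 was at 146 ± 15.7 against 0.0275 ± 0.0552 FPKM, and Hoxa6, without counts in those EBs, was at least 505-fold higher. Lamp5 was higher by 9.73 ± 0.18. The forebrain and midbrain gene Otx2 was lower by -8.68 ± 0.26, Otx1 was at 0.0075 ± 0.015 against 22.8 ± 12.1 FPKM, Sp5 at 0.04 ± 0.0523 against 15.7 ± 7.74 and Tnnt2 at 0.0225 ± 0.045 against 16.9 ± 20.3. T and Hbb-bh1 had no counts in NPCs, which put Hbb-bh1 at least 121-fold lower. Of 6061 genes past the threshold 2562 were higher in NPCs and 3499 lower. Hox genes were higher in 23 of 29 and lower in 2 (23 and 2 adjusted over the list alone, median 5.94, the same with 3 members at their bound, camera adjusted p = 9.4e-08, adjusted p = 0.10 with an estimated correlation). Neuronal genes were higher in 40 of 46 and lower in 1 (40 and 1 adjusted over the list alone, median 2.81, camera adjusted p = 2.7e-11, adjusted p = 0.10 with an estimated correlation). The neurofilament gene Ina was at 830 ± 49.1 FPKM (5.06 ± 0.12), Myt1l at 5.28 ± 0.13, Lhx3 at 5.06 ± 0.32 and Slc32a1 at 4.90 ± 0.19. Endoderm genes were lower in 26 of 33 (26 adjusted over the list alone, median -2.94, camera adjusted p = 6.8e-05, adjusted p = 0.62 with an estimated correlation). Apob was at -6.53 ± 0.96, Apoa1 at -5.67 ± 1.02, Ttr at -5.59 ± 0.67 and Spink1 at 0.065 ± 0.13 against 12.6 ± 7.67 FPKM. By limma on log2(FPKM + 1) 3814 genes passed.

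**Figure D2:**
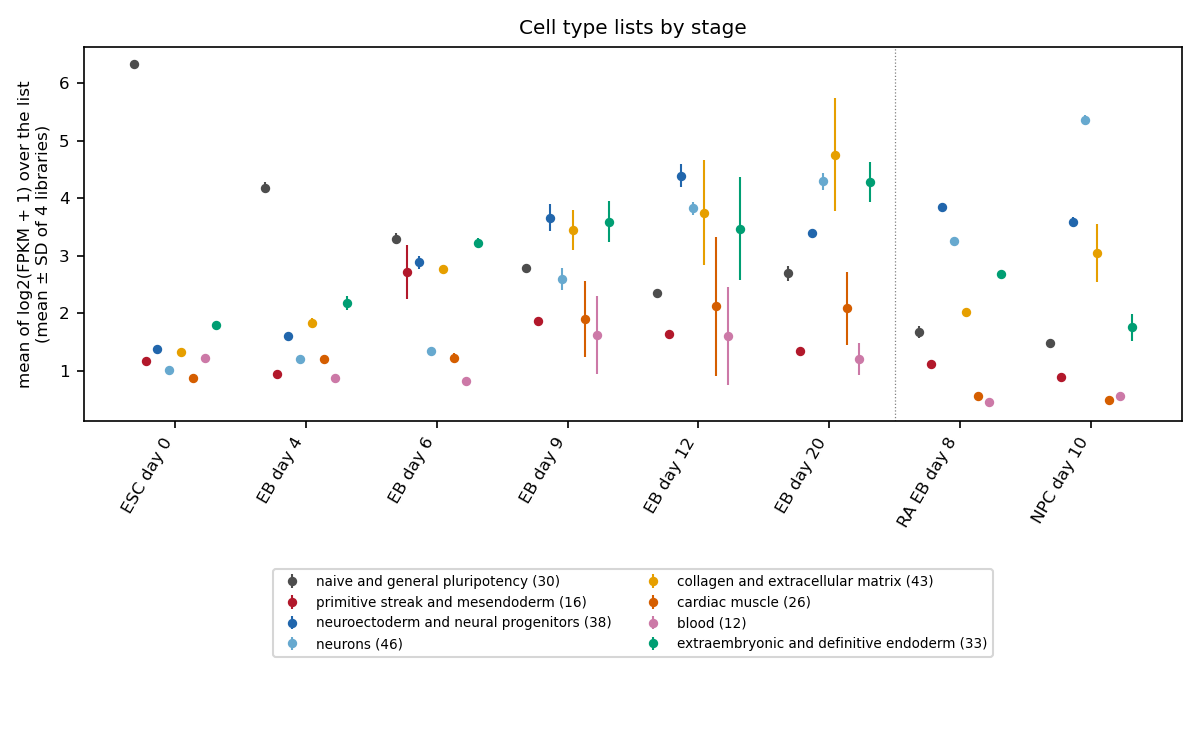
Mean of log2(FPKM + 1) over the members of 8 gene lists at each stage, as mean ± SD of the 4 libraries of a stage, with the number of members in the key. Pluripotency genes are highest in ESCs, neuronal genes in NPCs, and the matrix and cardiac lists spread widely between the libraries of EB days 12 and 20.

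The 24 bisphenol libraries were compared with the 8 DMSO libraries over all stages. In the bisphenol cultures Cer1 was higher by 2.85 ± 0.33 (adjusted p = 3.7e-05, higher in 6 of 8 stages) and Foxf2, a forkhead gene of the mesoderm (Entrez 14238, chromosome 13, 31625816 to 31631406), by 2.86 ± 0.35 (adjusted p = 3.7e-05, 6 of 8). Embryonic globin Hbb-bh1 was higher by 3.96 ± 0.60 (4 of 8 stages), the nodal cofactor gene Cfc1 by 2.56 ± 0.29 (7 of 8), Cyp2f2 by 2.89 ± 0.44 (5 of 8), Cped1 by 2.75 ± 0.43 (6 of 8), Lum by 2.63 ± 0.43 (5 of 8), Aplnr by 1.90 ± 0.29 (5 of 8), T by 1.75 ± 0.24 (5 of 8) and Corin by 1.45 ± 0.18 (6 of 8). The lower genes with the smallest p included Otx1 (Entrez 18423, chromosome 11, 21994764 to 22001651) by -1.08 ± 0.11 (adjusted p = 2e-06, 7 of 8 stages), Fezf1 by -1.67 ± 0.18 (7 of 8), Lhx9 by -1.28 ± 0.20 (6 of 8), Barhl1 by -0.96 ± 0.15 (5 of 8), Mab21l2 by -0.96 ± 0.14 (5 of 8), Sim2 by -0.95 ± 0.13 (6 of 8) and Lhx2 by -0.87 ± 0.13 (6 of 8). The Wnt agonist gene Rspo2 (-1.23 ± 0.18) and Lmo1 (-0.82 ± 0.11) were lower in 8 of 8 stages, and Serpina3n (-1.44 ± 0.15) in 6 of 8. Of 15632 genes 427 passed, 163 higher and 264 lower (77 and 14 of those with a change of 2-fold or more), with 2797 at an unadjusted p under 0.05.

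Of 26 cardiac genes 5 rose (10 adjusted over the list alone, median 0.97): atrial myosin Myl7 by 2.22 ± 0.54, troponin Tnni1 by 2.02 ± 0.42, Tbx20 by 1.91 ± 0.41 and Tbx5 by 1.25 ± 0.25. The camera adjusted p was 4.3e-10, but the adjusted p = 0.46 with an estimated correlation, a value shared by the matrix, endothelium, mesoderm, neuronal and neural progenitor lists. Matrix genes rose in 3 of 43 (3 adjusted over the list alone, median 0.34, camera adjusted p = 2.6e-08), Lum, Col9a1 (2.37 ± 0.44) and Vcan (0.48 ± 0.13). Mesoderm genes rose in 3 of 23 and fell in 1 (11 and 2 adjusted over the list alone, median 0.59, camera adjusted p = 3.5e-05). Meox2 was at 2.61 ± 0.60, Hand1 at 1.69 ± 0.46, Foxc1 at 1.28 ± 0.30 and the kidney gene Pax8 at -0.62 ± 0.15. Of 20 endothelial genes edgeR called 0 over all genes and 7 adjusted over the list alone (median 0.68, camera adjusted p = 7.7e-07). Fli1 stood at 1.52 ± 0.44, Cdh5 at 1.38 ± 0.42, Etv2 at 1.19 ± 0.36 and Kdr at 1.04 ± 0.32, with adjusted p of 0.057, 0.068, 0.068 and 0.074. Neuronal genes fell in 10 of 46 and rose in 3 (23 and 3 adjusted over the list alone, median -0.23, camera adjusted p = 0.00036). Slc32a1 was at -0.54 ± 0.15, while the motor neuron genes Isl1 (1 ± 0.23) and Mnx1 (0.64 ± 0.17) rose. Neural progenitor genes fell in 6 of 38 and rose in 1 (14 and 1 adjusted over the list alone, median -0.19, camera adjusted p = 0.0017). Olig2 was at -0.87 ± 0.23, Emx2 at -0.79 ± 0.19 and Zic1 at -0.65 ± 0.12. Genes of p53 and apoptosis fell in 9 of 24 (15 adjusted over the list alone, median -0.19, camera adjusted p = 3.2e-10, adjusted p = 0.19 with an estimated correlation). Pmaip1 was at -0.54 ± 0.12, Bbc3 at -0.36 ± 0.08, Eda2r at -0.32 ± 0.06 and Cdkn1a at -0.29 ± 0.07.

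Receptor pathways linked to bisphenols moved little over all stages. Of 22 nuclear receptor genes edgeR called 0 (1 adjusted over the list alone, median 0.04, camera adjusted p = 0.24), of 21 estrogen response genes 1, which fell (1 adjusted over the list alone, median 0.06, camera adjusted p = 0.24), and of 16 xenobiotic genes 0 (0 adjusted over the list alone, median -0.05, camera adjusted p = 0.47). Wnt, BMP and Notch genes rose in 4 of 41 and fell in 3 (8 and 7 adjusted over the list alone, median 0.05, camera adjusted p = 0.47). The total of 427 rested on the middle and late EBs: it was 202 without EB day 6, 42 without EB day 9, 37 without EB day 12, 144 without EB day 20 and 1103 without NPC day 10. With limma on log2(FPKM + 1) it was 11, with Lmo1 the only one of the 20 leading genes kept, and DESeq2 called 362.

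BPA against DMSO called 26 genes, 16 higher and 10 lower, with 1611 at an unadjusted p under 0.05. Higher were Foxf2 (2.85 ± 0.39, adjusted p = 0.0003, 7 of 8 stages), Cped1 (2.62 ± 0.47), Lum (2.60 ± 0.48), Cer1 (2.33 ± 0.37), Cfc1 (2.21 ± 0.34), T (1.86 ± 0.28), Ferd3l (1.80 ± 0.30), Corin (1.54 ± 0.21), Gpr37 (1.42 ± 0.28) and Shh (1.11 ± 0.24). Lower were Otx1 (-1.05 ± 0.14, adjusted p = 0.0003, 7 of 8 stages), Fezf1 (-1.69 ± 0.23), Serpina3n (-1.60 ± 0.21), Shox2 (-1.10 ± 0.23), Mab21l2 (-0.88 ± 0.18), Lhx2 (-0.85 ± 0.16), the endocytic receptor gene Lrp2 (-0.55 ± 0.12), Dusp8 (-0.44 ± 0.09), Slc22a23 (-0.30 ± 0.06) and Susd6 (-0.25 ± 0.05). Matrix genes rose in 1 of 43 (2 adjusted over the list alone, median 0.19, camera adjusted p = 1.5e-05, adjusted p = 0.74 with an estimated correlation), and neural progenitor genes fell in 1 of 38 (5 lower and 1 higher adjusted over the list alone, median -0.16, camera adjusted p = 0.0012, adjusted p = 0.72 with an estimated correlation). The count was 17 without EB day 4, 11 without EB day 6, 9 without EB day 9, 7 without EB day 12, 8 without EB day 20, 42 without RA EB day 8 and 121 without NPC day 10, and of the genes named only Foxf2, Cer1, Otx1, Serpina3n and Fezf1 stayed called whichever stage was left out. DESeq2 called 13 genes, with the majority turned (5 higher and 8 lower), and limma on log2(FPKM + 1) 0.

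BPF against DMSO called 155 genes, 66 higher and 89 lower (51 and 20 at 2-fold or more), with 2199 at an unadjusted p under 0.05. Cer1 (3.28 ± 0.37, adjusted p = 7e-05), Hbb-bh1 (4.31 ± 0.63), Pax1 (4.20 ± 0.76), Cyp2f2 (3.11 ± 0.48), Foxf2 (2.88 ± 0.39), Cfc1 (2.84 ± 0.32), Cped1 (2.76 ± 0.47), Aplnr (2.01 ± 0.33), T (1.78 ± 0.28) and Corin (1.48 ± 0.21) were higher. Fezf1 (-1.63 ± 0.24), Serpina3n (-1.55 ± 0.20), Epha8 (-1.31 ± 0.22), Barhl1 (-1.21 ± 0.19), Otx1 (-1.11 ± 0.14, adjusted p = 0.00011), Mab21l2 (-1.03 ± 0.18), Lhx2 (-0.97 ± 0.16), Lmo1 (-0.91 ± 0.15), Sim2 (-0.88 ± 0.16) and Ptprt (-0.63 ± 0.12) were lower. Cardiac genes rose in 4 of 26 (10 adjusted over the list alone, median 1, camera adjusted p = 1.8e-10, adjusted p = 0.53 with an estimated correlation): Myl7 by 2.39 ± 0.60, Tnni1 by 2.35 ± 0.46, Tbx20 by 2.17 ± 0.45 and Tbx5 by 1.19 ± 0.29. The count was 48 without EB day 6, 12 without EB day 9, 15 without EB day 12 (9 higher and 6 lower, 72 and 68 without EB day 4), 41 without EB day 20, 241 without RA EB day 8, 567 without NPC day 10 and 96 with a filter of 5 CPM. DESeq2 called 90 and limma on log2(FPKM + 1) 0, and each of the 4 cardiac genes lost its call without EB day 9 or EB day 12.

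BPS against DMSO called 179 genes, 97 higher and 82 lower (73 and 10 at 2-fold or more), with 2577 at an unadjusted p under 0.05. Hbb-bh1 (Entrez 15132, chromosome 7, 103841638 to 103843162) was higher by 6.01 ± 0.61 (adjusted p = 0.00011), followed by Pax1 (4.38 ± 0.75), Cyp2f2 (3.27 ± 0.48), Cer1 (2.94 ± 0.36), Cped1 (2.88 ± 0.47), Foxf2 (2.86 ± 0.39), Tnni1 (2.84 ± 0.46), Cfc1 (2.62 ± 0.33), Aplnr (2.16 ± 0.33) and Corin (1.33 ± 0.21). Fezf1 (-1.70 ± 0.24), Wnt8b (-1.59 ± 0.31), Rspo2 (-1.38 ± 0.24), Sim2 (-1.29 ± 0.17), Serpina3n (-1.17 ± 0.20), Otx1 (-1.07 ± 0.14), Mab21l2 (-0.98 ± 0.18), Lmo1 (-0.95 ± 0.15), Fam181b (-0.81 ± 0.16) and Dusp8 (-0.45 ± 0.09) were lower. Cardiac genes rose in 11 of 26 (23 adjusted over the list alone, median 1.59, camera adjusted p = 7.4e-14, adjusted p = 0.28 with an estimated correlation). Pln was at 3.52 ± 0.72, Myl7 at 3.26 ± 0.59 and Tnnt2 at 3.23 ± 0.70. Blood genes rose in 3 of 12 (5 adjusted over the list alone, median 0.45, camera adjusted p = 0.0036, adjusted p = 0.33 with an estimated correlation), all globins, with Hba-x at 5.26 ± 1.05 and Hba-a1 at 4.64 ± 0.91. Endothelial genes rose in 1 of 20 (10 adjusted over the list alone, median 0.93, camera adjusted p = 3.5e-08, adjusted p = 0.33 with an estimated correlation), Cdh5 (1.92 ± 0.47). The count was 279 without EB day 4, 53 without EB day 6, 9 without EB day 9, 12 without EB day 12, 86 without EB day 20, 275 without RA EB day 8, 749 without NPC day 10, 336 over the 6 stages after EB day 4 and 101 with a filter of 5 CPM. DESeq2 called 172, with the majority turned (61 higher and 111 lower; 132 and 133 with length and GC trends removed), and limma on log2(FPKM + 1) called 0, and Tnnt2 and Myl7 lost their calls without EB day 9 or EB day 12.

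The 3 compounds are structural analogs and were compared at the same 100 nM over all stages. Otx1 fell alike: BPA differed from BPF by 0.07 ± 0.14 and from BPS by 0.03 ± 0.14. Foxf2 differed by -0.03 ± 0.31 and -0.01 ± 0.33. Hbb-bh1 was lower with BPA than with BPS and was the 1 gene called in that comparison, where edgeR had 1075 genes at an unadjusted p under 0.05. Between BPA and BPF, and between BPF and BPS, edgeR called 0 genes (336 and 266 at an unadjusted p under 0.05), and limma and DESeq2 called 0 in each of the 3 comparisons. The 95% interval of the difference lay within 1 log2 unit of 0 for 92.1% of genes between BPA and BPF, 91.4% between BPA and BPS and 92.7% between BPF and BPS. Leaving out each stage in turn gave 0 to 2 genes between BPA and BPS, a filter of 5 CPM gave 0 and the 6 stages after EB day 4 gave 2.

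A fit of the 24 bisphenol libraries without DMSO, chosen after seeing the data, called 4 genes lower with BPA than with BPF, 146 between BPA and BPS (20 higher and 126 lower with BPA) and 1 between BPF and BPS. With BPA, Hbb-bh1 was lower than with BPF by -2.81 (95% interval -3.61 to -2.02, adjusted p = 0.0048) and Tnni1 by -1.62 (-2.07 to -1.17, adjusted p = 0.0024), as were Upk1b (-1.40, -1.88 to -0.91) and Cer1 (-0.94, -1.28 to -0.61). Against BPS, Hbb-bh1 was lower by -4.61 (-5.35 to -3.88, adjusted p = 1.2e-06), Tnni1 by -2.15 (-2.58 to -1.71), Tnnt2 by -2.54 (-3.20 to -1.88), Gata4 by -1.01 (-1.30 to -0.73) and Myh6 by -2.15 (-2.77 to -1.53), while Sim2 was higher by 0.66 (0.38 to 0.93). Cardiac genes were lower with BPA than BPS in 21 of 26 (23 adjusted over the list alone, median -1.13, camera adjusted p = 4.7e-15, adjusted p = 0.36 with an estimated correlation). Hbb-bh1 was lower with BPF than BPS by -1.80 (-2.36 to -1.24). Named genes went this way in 3 to 7 of 8 stages.

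Changes against DMSO correlated across 15632 genes, which are not independent replicates, with r = 0.75 between BPA and BPF, 0.71 between BPA and BPS and 0.80 between BPF and BPS. The compounds share their DMSO libraries, and simulations without any effect gave 0.51, 0.50 and 0.51. The covariances were 0.0418, 0.0417 and 0.0530 against 0.0118, 0.0117 and 0.0117 in those simulations. With the 8 stages divided into 2 sets of 4, so that no DMSO library served both sides, the mean r over 35 divisions was 0.15 (-0.14 to 0.29), 0.15 (-0.13 to 0.28) and 0.18 (-0.20 to 0.35). By the chi-square per degree of freedom of the counts between pairs of libraries, DMSO lay farther from the bisphenol libraries than these lay from each other in 7 of 8 stages (mean difference 7.84, SD 7.49, exact two-sided sign-flip p = 0.0156, adjusted p = 0.0624 over 4 tests). The values rose in the global branch from 8.58 against 4.06 at EB day 6 to 26.6 against 6.39 at EB day 20, while in ESCs they were 2.58 against 3.03.

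**Figure D3:**
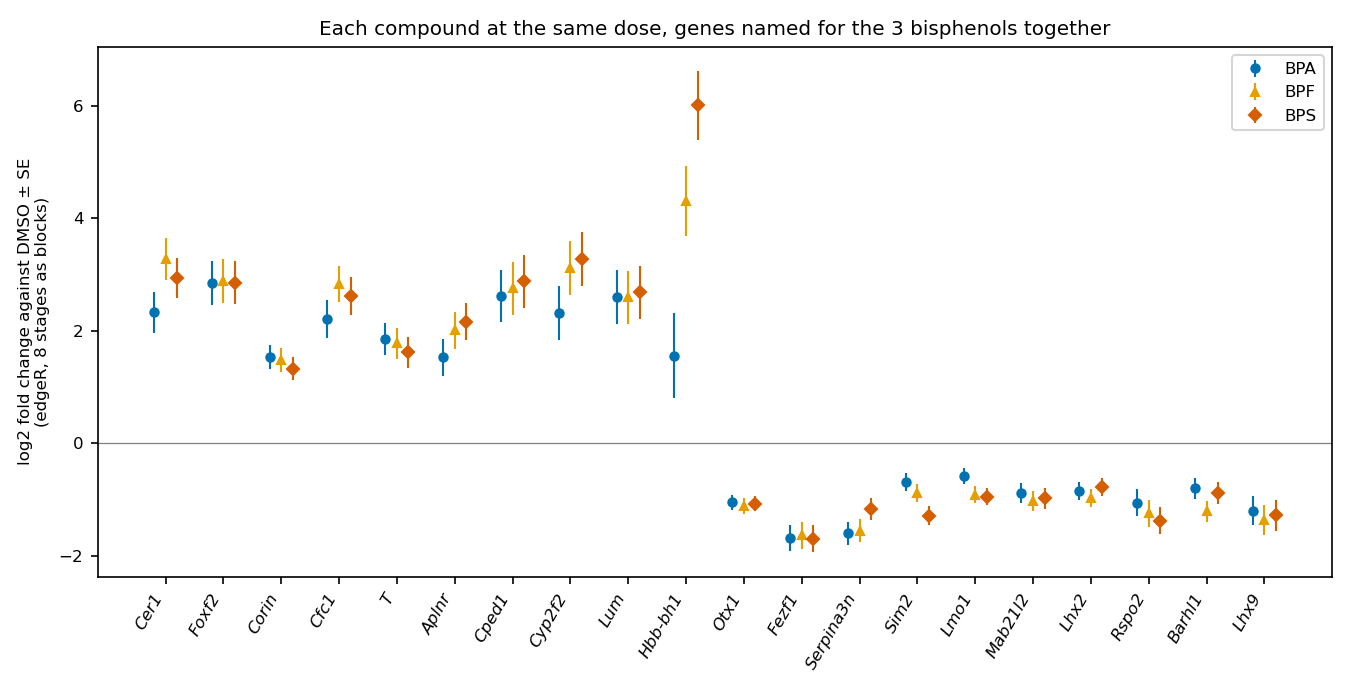
Log2 change against DMSO across stages, ± SE, of the 20 genes named for the 3 bisphenols together, 1 colour per compound. Otx1 and Foxf2 lie close for the 3 compounds, while Hbb-bh1 is at 6.01 with BPS and 4.31 with BPF.

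**Figure D4:**
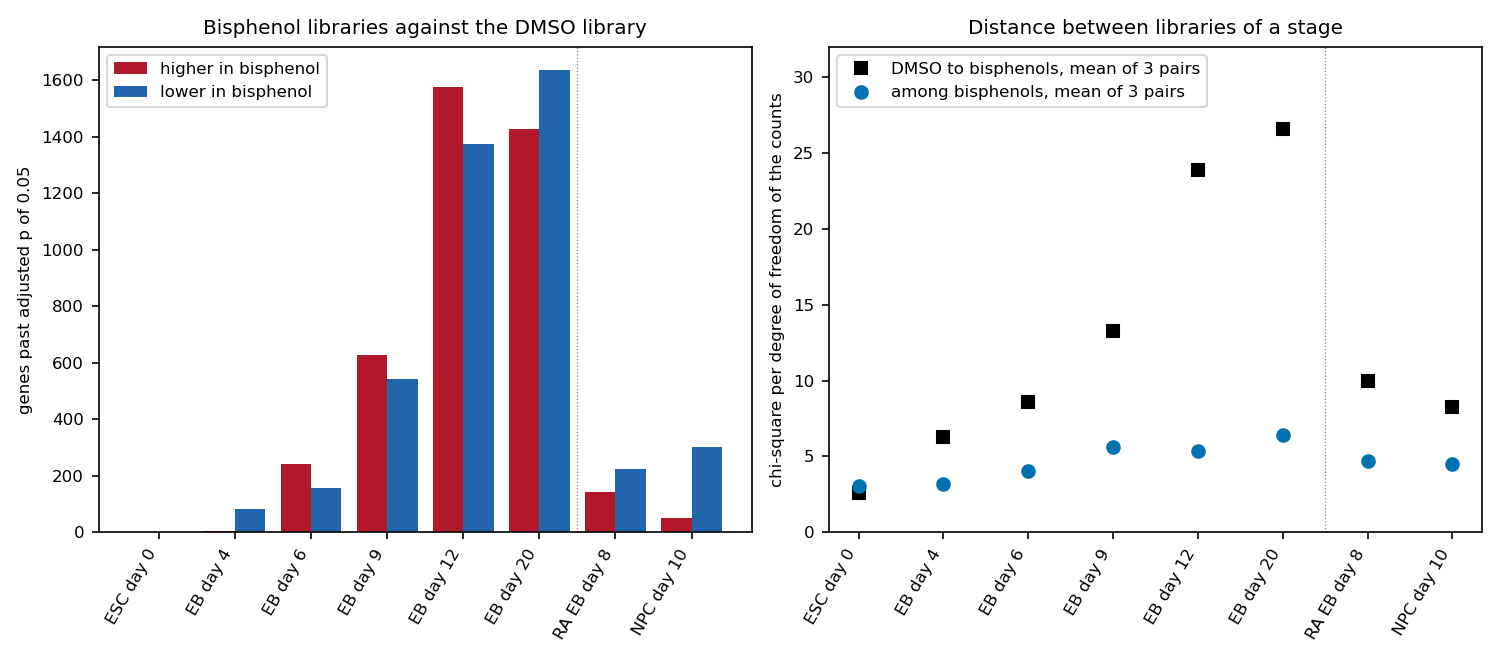
Left, genes past an adjusted p of 0.05 at each stage, higher and lower with bisphenols. Right, chi-square per degree of freedom of the counts between libraries of a stage, as the mean of 3 pairs from DMSO to bisphenols and the mean of 3 pairs among bisphenols, with 26.6 against 6.39 at EB day 20.

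At single stages the 3 bisphenol libraries were set against the 1 DMSO library, which was assumed to vary as the others do. Levels here are mean FPKM ± SD of the 3 bisphenol libraries against the DMSO value. In ESCs, before differentiation, edgeR and DESeq2 called 0 genes and limma on log2(FPKM + 1) 1, with 257 at an unadjusted p under 0.05. The smallest p values, none past the threshold (adjusted p = 1), were those of Lig4 (0.46), Clasp1 (0.34), Tdg (0.67), Zkscan2 (0.86) and Gmip (-0.94). Of 30 pluripotency genes 0 were called in edgeR (0 adjusted over the list alone, median 0.02, camera adjusted p = 0.99).

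At EB day 4, 5 genes were higher and 83 lower. The stress gene Nupr1 (-1.67 ± 0.39), Ndufa4l2 (-1.40 ± 0.27), the large cytoskeletal genes Ahnak (-1.20 ± 0.25) and Dst (-1.19 ± 0.18, adjusted p = 0.00082) and perlecan, Hspg2 (-1.09 ± 0.22), fell. Capn12 (0.73 ± 0.15), Atp5k (0.57 ± 0.13), Bex4 (0.56 ± 0.12), Upf3b (0.55 ± 0.13) and the kinase Pim2 (0.52 ± 0.12) rose. Of 43 matrix genes 0 were called in edgeR (1 adjusted over the list alone), though their median was -0.29 (camera adjusted p = 2.3e-06, adjusted p = 0.68 with an estimated correlation). Fibronectin, Fn1, was at -0.87 ± 0.23 (adjusted p = 0.086). In the pluripotency list 1 of 30 fell (4 adjusted over the list alone, median -0.15, camera adjusted p = 0.052). The total was 26 without BPF, 158 with DESeq2 and 17 with length and GC trends removed, where Dst and Ndufa4l2 alone of the 10 genes stayed called.

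At EB day 6 primitive streak genes were higher in the bisphenol EBs. Lhx1 rose by 3.72 ± 0.49, Cer1 by 3.16 ± 0.32 to 92.1 ± 26.7 against 10.2 FPKM (adjusted p = 3.2e-06), T by 2.37 ± 0.29 to 54.2 ± 7.19 against 10.3 and Foxa2 by 1.76 ± 0.19. The list rose in 6 of 16 (8 adjusted over the list alone, median 1.04, camera adjusted p = 3.2e-05, and 0.0087 with an estimated correlation). Lgr5 (3.24 ± 0.39), Cfc1 (3.18 ± 0.46) and Samd3 (3.07 ± 0.35) rose as well. Forebrain genes Fezf2 (-2.44 ± 0.35) and Wnt8b (-1.83 ± 0.26), the progenitor gene Dbx1 (-1.56 ± 0.24), Sez6 (-1.44 ± 0.16) and Postn (-1.40 ± 0.21) fell. Neural progenitor genes fell in 8 of 38 and rose in 1 (13 and 2 adjusted over the list alone, median -0.17, camera adjusted p = 0.00023, adjusted p = 0.18 with an estimated correlation). Pax6 was at -1.60 ± 0.18, Emx2 at -1.53 ± 0.30 and Lhx2 at -1.15 ± 0.20. Of 399 genes 242 were higher and 157 lower, and the total was 784 without BPA, 107 without BPF and 201 without BPS.

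At EB day 9 vascular, mesodermal and matrix genes were higher in the bisphenol EBs and neural genes lower. Pax1 was at 15.3 ± 7.62 against 0.04 FPKM (adjusted p = 2.8e-05), and Vgll2 (4.93 ± 0.78), Cd34 (3.29 ± 0.46), Plvap (3.22 ± 0.61) and Cdh5 (3.07 ± 0.73) rose. Wnt8b (-2.54 ± 0.25), Rspo2 (-2.15 ± 0.26), Tfap2b (-1.92 ± 0.21) and Rspo3 (-1.91 ± 0.19) fell, and the histone gene H2ac13, without counts in the bisphenol EBs, was at least 52.9-fold lower. Endothelial genes rose in 14 of 20 (18 adjusted over the list alone, median 2.40, camera adjusted p = 7.1e-15, and 0.046 with an estimated correlation). Tie1 was at 4.15 ± 0.76, Fli1 at 3.60 ± 0.77 and Emcn at 3.39 ± 0.71. Matrix genes rose in 23 of 43 and fell in 1 (28 and 1 adjusted over the list alone, median 0.72, camera adjusted p = 7.1e-15, and 0.046 with an estimated correlation). Col9a1 was at 2.83 ± 0.52, Col3a1 at 2.61 ± 0.17 and Lum at 2.58 ± 0.28. Mesoderm genes rose in 12 of 23 and fell in 1 (15 and 1 adjusted over the list alone, median 1.34, camera adjusted p = 1.4e-08, and 0.046 with an estimated correlation). Kdr was at 2.87 ± 0.57 and Pdgfrb at 2.37 ± 0.27. Neural progenitor genes fell in 20 of 38 and rose in 1 (24 and 1 adjusted over the list alone, median -0.54, camera adjusted p = 1.6e-09, and 0.037 with an estimated correlation): Emx2 by -1.91 ± 0.32, Olig2 by -1.87 ± 0.27 and Pax6 by -1.62 ± 0.16. Neuronal genes fell in 19 of 46 and rose in 2 (26 and 5 adjusted over the list alone, median -0.59, camera adjusted p = 3.1e-09, and 0.046 with an estimated correlation). Syt1 was at -1.30 ± 0.26, Rbfox3 at -1.27 ± 0.21 and Isl1 at 1.79 ± 0.43. Genes of p53 and apoptosis fell in 12 of 24 (14 adjusted over the list alone, median -0.36, camera adjusted p = 3.1e-09, adjusted p = 0.053 with an estimated correlation), led by Pmaip1 (-1.15 ± 0.19). Of 1171 genes 627 were higher and 544 lower, a majority that turned without a filter (545 and 638) and without BPS (318 and 348), and the total was 1985 without BPA, 504 without BPF and 666 without BPS. Without BPF Cdh5 and Isl1 were not called.

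At EB day 12 matrix, smooth muscle and heart genes were higher in the bisphenol EBs. Smooth muscle actin, Acta2 (Entrez 11475, chromosome 19, 34240336 to 34255585), was at 273 ± 71.9 against 11.3 FPKM (4.56 ± 0.41, adjusted p = 1.1e-08), Tnnt2 at 30.4 ± 27.5 against 0.09 and Cnn1 at 8.47 ± 2.65 against 0.05. Myh6 rose by 8.06 ± 1.69, and Hba-a1 and H2ac13, without counts in DMSO, were at least 32.1-fold and at least 12.0-fold higher. H2ac13 had gone the other way in the EB stage before. Wfdc1 (-2.21 ± 0.36), Rasgrp1 (-2.05 ± 0.22), Shisa8 (-2.04 ± 0.27) and the neuronal noncoding RNAs Miat (-2.06 ± 0.25) and Mir124a-1hg (-1.96 ± 0.32) fell. Matrix genes rose in 40 of 43 (40 adjusted over the list alone, median 2.37, camera adjusted p = 9.2e-46, and 0.00054 with an estimated correlation). Tnc was at 5.32 ± 0.60 and Lox at 4.82 ± 0.38. Smooth muscle genes rose in 15 of 16 (15 adjusted over the list alone, median 2.84, camera adjusted p = 2.8e-20, and 0.011 with an estimated correlation). Actg2 was at 5.35 ± 0.61 and Tagln at 4.34 ± 0.39. Fibroblast genes rose in 12 of 17 (12 adjusted over the list alone, median 3.15, the same with 2 members at their bound, camera adjusted p = 5.9e-17, and 0.00054 with an estimated correlation). Col1a2 was at 4.71 ± 0.27 and Twist2 at 4.41 ± 0.62. Mesoderm genes rose in 16 of 23 (18, with 1 lower, adjusted over the list alone, median 2.69, camera adjusted p = 5.6e-15, and 0.0079 with an estimated correlation). Tbx18 was at 4.41 ± 0.69, and Osr1 was at 5.93 ± 1.02 against 0.10 FPKM. Cardiac genes rose in 22 of 26 (24 adjusted over the list alone, median 4.14, or 3.88 with 2 members at their bound, camera adjusted p = 1.1e-16, adjusted p = 0.086 with an estimated correlation); Ttn and Pln, without counts in DMSO, were at least 29.7-fold and at least 9.57-fold higher.

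Immediate early genes rose in 14 of 26 and fell in 1 (15 and 1 adjusted over the list alone, median 1.08, camera adjusted p = 9.8e-11, and 0.037 with an estimated correlation). Ccn1 was at 2.5 ± 0.26, Ccn2 at 2.45 ± 0.36 and Egr1 at 2.21 ± 0.27. Retinoic acid targets rose in 13 of 27 and fell in 2 (18 and 2 adjusted over the list alone, median 1.12, camera adjusted p = 5.6e-07, and 0.037 with an estimated correlation). Aldh1a2 was at 3.53 ± 0.66 and Rarb at 2.63 ± 0.28. Estrogen response genes rose in 10 of 21 and fell in 3 (10 and 4 adjusted over the list alone, median 0.46, the same with 1 member at its bound, camera adjusted p = 0.00047, and 0.037 with an estimated correlation). Igf1 was at 4.01 ± 0.62 and Cxcl12 at 2.79 ± 0.26, which are also mesenchymal genes. Of 22 nuclear receptor genes 3 rose (5 adjusted over the list alone, median 0.27, camera adjusted p = 0.027, adjusted p = 0.11 with an estimated correlation): Ahr by 2.16 ± 0.27, Nr3c1 by 0.80 ± 0.17 and Rxra by 0.33 ± 0.11. Of 16 xenobiotic genes 2 rose (2 adjusted over the list alone, median 0.26, or 0.01 with 4 members at their bound, camera adjusted p = 0.035, adjusted p = 0.087 with an estimated correlation), Cyp1b1 (2.52 ± 0.20) and Tiparp (0.57 ± 0.12). Neural progenitor genes fell in 23 of 38 and rose in 2 (25 and 3 adjusted over the list alone, median -0.55, camera adjusted p = 1.8e-05, adjusted p = 0.058 with an estimated correlation). Olig2 was at -1.63 ± 0.23, Lhx2 at -1.35 ± 0.16 and En1 at 1.41 ± 0.35. Of 2951 genes 1577 were higher and 1374 lower, and the total was 1666 without BPF.

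At EB day 20 matrix genes stayed higher in the bisphenol EBs. Collagen Col1a1 (Entrez 12842, chromosome 11, 94936224 to 94953042) was at 452 ± 65.8 against 34.8 FPKM (3.64 ± 0.30, adjusted p = 1.6e-09) and Lox at 106 ± 16.4 against 6.18 (4.06 ± 0.23). Osr1 (4.92 ± 0.50) and Cpz (4.49 ± 0.50) rose, Mfap5 was at 6.93 ± 0.936 against 0.07 FPKM, and Cers1, without counts in DMSO, was at least 95.3-fold higher. Its neighbour Gdf1 (-1.97 ± 0.63), the crystallins Cryge (-4.10 ± 0.59) and Cryaa (-1.89 ± 0.45), Tfap2d (-2.10 ± 0.30) and Lhx9 (-1.85 ± 0.23) fell. How reads divide between Cers1 and Gdf1 was not tested. Matrix genes rose in 37 of 43 (38 adjusted over the list alone, median 2.5, camera adjusted p = 1.8e-41, and 0.00093 with an estimated correlation), smooth muscle genes in 15 of 16 (16 adjusted over the list alone, median 2.33, camera adjusted p = 1.4e-23, and 0.0056 with an estimated correlation) and fibroblast genes in 13 of 17 (13 adjusted over the list alone, median 3.53, or 2.72 with 2 members at their bound, camera adjusted p = 7.1e-19, and 0.00053 with an estimated correlation). Among them were Mfap4 (4.09 ± 0.27), Myh11 (3.69 ± 0.51), Mylk (3.47 ± 0.24), Igfbp7 (3.91 ± 0.29) and Mgp (3.72 ± 0.41). Mesoderm genes rose in 13 of 23 (14 adjusted over the list alone, median 2.06, or 2.05 with 1 member at its bound, camera adjusted p = 1.1e-10, and 0.020 with an estimated correlation). Foxc1 was at 3.30 ± 0.41. Wnt, BMP and Notch genes rose in 14 of 41 and fell in 3 (15 and 4 adjusted over the list alone, median 0.42, or 0.37 with 1 member at its bound, camera adjusted p = 8.7e-05, and 0.0056 with an estimated correlation). Dkk2 was at 2.93 ± 0.37 and Bmp4 at 2.41 ± 0.29. Xenobiotic genes rose in 5 of 16 and fell in 1 (5 and 1 adjusted over the list alone, median 0.51, camera adjusted p = 0.011, and 0.044 with an estimated correlation): Cyp1b1 (Entrez 13078, chromosome 17, 79706940 to 79715061) by 2.10 ± 0.19, Gstm2 by 1.98 ± 0.28 and Nqo1 by 1.07 ± 0.26. Neuronal genes fell in 15 of 46 (17, with 1 higher, adjusted over the list alone, median -0.33, camera adjusted p = 0.0084, adjusted p = 0.46 with an estimated correlation). Gad2 was at -0.97 ± 0.17 and Gad1 at -0.80 ± 0.14. Of 3064 genes 1428 were higher and 1636 lower (809 and 94 at 2-fold or more), a majority kept without BPA and turned in the other alternatives (1469 and 1414 with DESeq2 size factors, 1690 and 1096 with limma), and the total was 1396 without BPF.

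In RA EBs of day 8, 141 genes were higher and 225 lower with bisphenols. The falls with the largest change were those of the noncoding RNA Bc1 (-1.67 ± 0.26), Oaz1 (-1.52 ± 0.30), Krtcap2 (-1.46 ± 0.17), Cox8a (-1.36 ± 0.13, adjusted p = 2.1e-06) and Mt1 (-1.31 ± 0.27). Prex2 (1.43 ± 0.23), H2ac22 (0.86 ± 0.22), Carmil1 (0.77 ± 0.15) and Zfp51 (0.77 ± 0.18) rose, and H2ac24, without counts in DMSO, was at least 343-fold higher. The neuronal, Hox, retinoic acid target and matrix lists had 0 calls in edgeR (0 adjusted over the list alone in each), with medians of -0.06, -0.07, -0.04 and -0.01 and camera adjusted p of 0.64, 0.71, 0.95 and 0.64. The total was 104 without BPF, 111 without BPS and 566 with limma on log2(FPKM + 1) (117 higher and 449 lower), and the majority turned with length and GC trends removed (289 higher and 248 lower).

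In NPCs of day 10 matrix genes were lower with bisphenols, the opposite of EB days 9, 12 and 20. Inhba (-2.14 ± 0.37), Actg2 (-2.02 ± 0.41), Emp1 (-1.93 ± 0.20, adjusted p = 1.6e-06), Sfn (-1.86 ± 0.49) and Fbln5 (-1.78 ± 0.24) fell. Lin28a (0.92 ± 0.21), Igdcc3 (0.91 ± 0.17), Cox8a (0.85 ± 0.17), Tmem258 (0.84 ± 0.23) and Tmem129 (0.82 ± 0.17) rose, and H2ac24, without counts in the bisphenol NPCs, was at least 284-fold lower. H2ac24 had gone the other way in RA EBs, and its share of reads was not tested. Matrix genes fell in 32 of 43 (36 adjusted over the list alone, median -1.19, or -1.16 with 1 member at its bound, camera adjusted p = 7e-40, and 0.0023 with an estimated correlation). Tnc was at -1.74 ± 0.32 and Thbs1 at -1.69 ± 0.26. Fibroblast genes fell in 8 of 17 (11 adjusted over the list alone, median -1.18, the same with 1 member at its bound, camera adjusted p = 2.5e-09, and 0.012 with an estimated correlation). Col1a1 was at -1.58 ± 0.23 and Dcn at -1.34 ± 0.17. Smooth muscle genes fell in 7 of 16 (12 adjusted over the list alone, median -0.92, camera adjusted p = 3.6e-13, adjusted p = 0.055 with an estimated correlation). Acta2 was at -1.42 ± 0.29. Surface ectoderm genes fell in 4 of 22 (10 adjusted over the list alone, median -1.15, the same with 1 member at its bound, camera adjusted p = 3.5e-12, adjusted p = 0.16 with an estimated correlation). Itgb4 was at -1.84 ± 0.32 and Perp at -1.61 ± 0.26. In the xenobiotic list 1 of 16 fell (3 adjusted over the list alone, median -0.17, or -0.07 with 4 members at their bound, camera adjusted p = 0.0026, and 0.028 with an estimated correlation), Cyp1b1 (-1.14 ± 0.15). Neural progenitor genes rose in 2 of 38 (4 adjusted over the list alone, median 0.20, camera adjusted p = 0.019, adjusted p = 0.33 with an estimated correlation), Pax6 (0.56 ± 0.13) and Irx3 (0.50 ± 0.13). Of 46 neuronal genes 0 were called in edgeR (0 adjusted over the list alone, median 0.15, camera adjusted p = 0.076). Of 352 genes 49 were higher and 303 lower; the total was 529 without BPA and 111 without BPF, where Actg2, Tnc, Acta2 and Pax6 were not called.

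**Figure D5:**
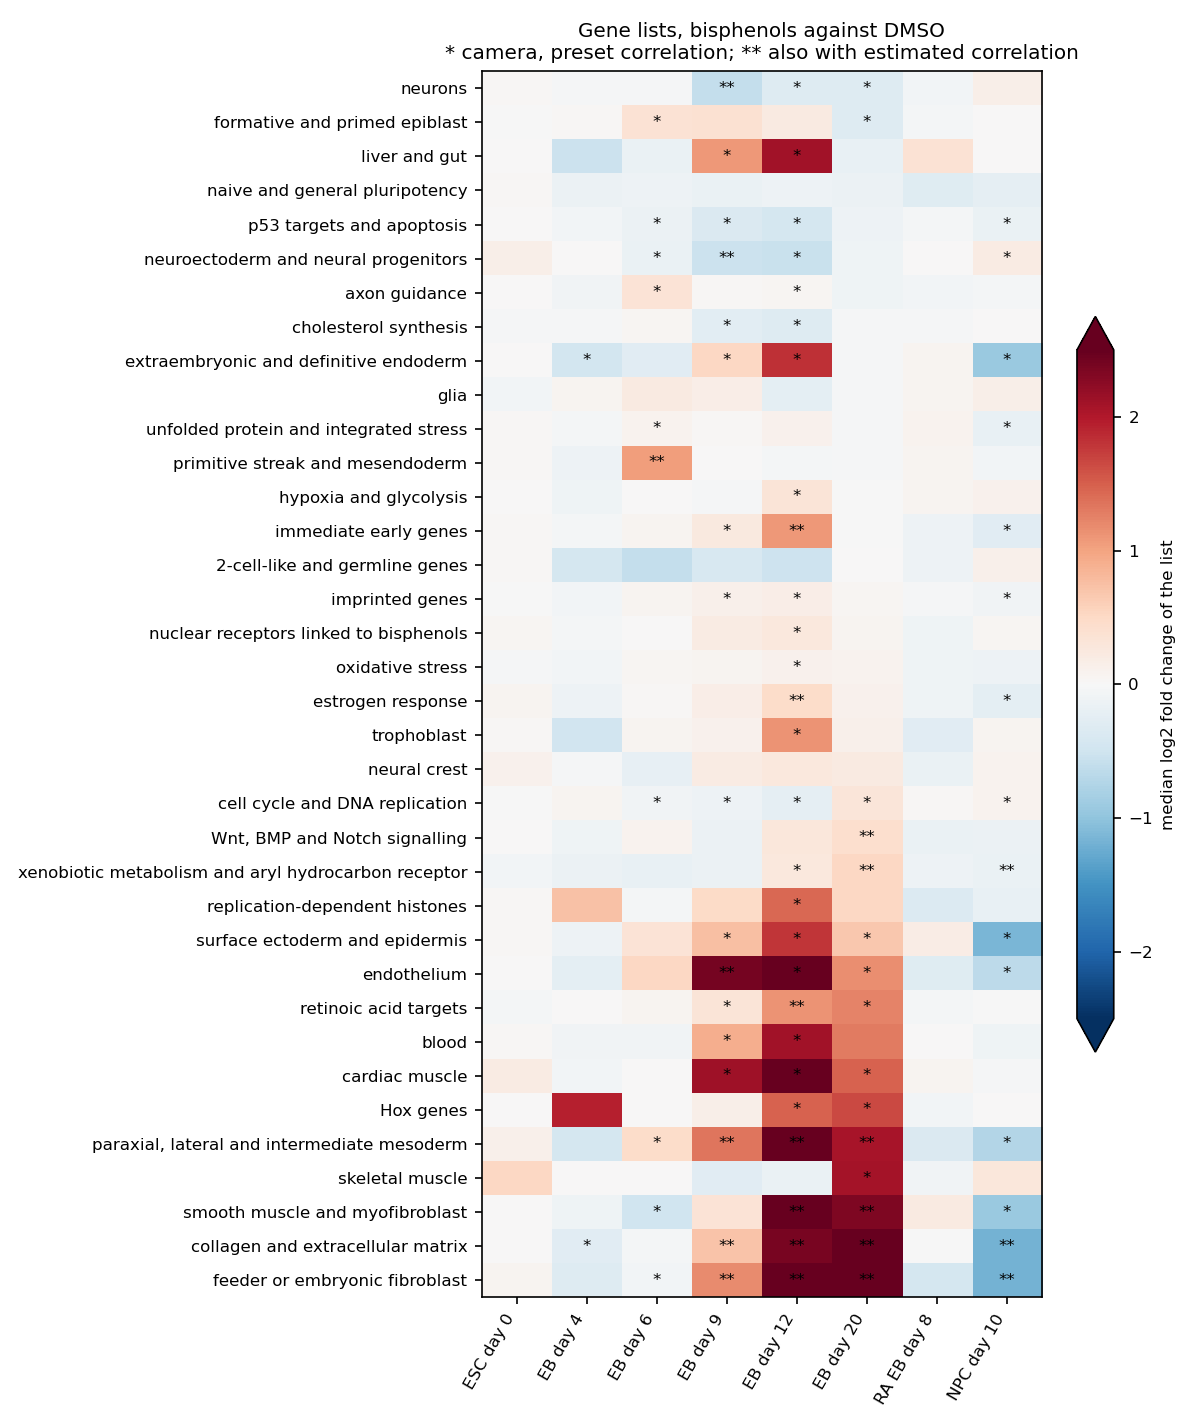
Median log2 change of each gene list, bisphenols against DMSO, at each stage, with colours saturating at 2.5 in either direction. One star marks a camera adjusted p under 0.05 and a pair of stars a call that also held with an estimated correlation.

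The bisphenol effect was compared between branches by an interaction term. RA EB and NPC effects did not correlate across genes (r = 0). Lox (Entrez 16948, chromosome 18, 52516060 to 52529867) responded more in the global branch by 5.40 ± 0.48 (adjusted p = 1.9e-06), as did Col6a3 (4.4 ± 0.46), Ddr2 (4.27 ± 0.43), Dcn (4.12 ± 0.40), Pear1 (3.85 ± 0.39), Smoc2 (3.40 ± 0.33), Hoxa5 (3.37 ± 0.39), Islr (2.82 ± 0.34), Prrx1 (2.58 ± 0.29) and Tmem176b (1.32 ± 0.14). Pax6 (Entrez 18508, chromosome 2, 105668896 to 105698410) responded less there by -1.53 ± 0.18 (adjusted p = 3.6e-05), as did Onecut1 by -1.81 ± 0.28, Onecut2 by -1.41 ± 0.21, Scrt1 by -0.99 ± 0.15, Srrm3 by -0.97 ± 0.15, Nuak2 by -0.93 ± 0.15, Pou3f3 by -0.84 ± 0.11, Ccdc88c by -0.78 ± 0.12, Stox2 by -0.67 ± 0.10 and Lyar by -0.65 ± 0.11. Matrix genes had the higher response in 28 of 42 (38 adjusted over the list alone, median 2.05, camera adjusted p = 1.4e-24), mesoderm genes in 13 of 23 (18, with 1 lower, adjusted over the list alone, median 2.25, camera adjusted p = 2.9e-14), endothelial genes in 10 of 20 (11 adjusted over the list alone, median 1.72, camera adjusted p = 5.7e-10), fibroblast genes in 10 of 16 (12 adjusted over the list alone, median 2.87, camera adjusted p = 4.6e-09) and Hox genes in 11 of 26 (11 adjusted over the list alone, median 1.28, camera adjusted p = 6.2e-05). Neural progenitor genes had the lower response in 13 of 38 (18 adjusted over the list alone, median -0.49, camera adjusted p = 8e-06), Dbx1 (-1.33 ± 0.22) and Pax7 (-1.51 ± 0.34) among them. For all 6 lists adjusted p = 0.16 with an estimated correlation. Of 1326 genes 724 had the higher and 602 the lower response in the global branch, and the total was 675 without EB day 12, 756 without RA EB day 8 and 508 without NPC day 10, where Lox, Dcn, Col6a3 and Pax7 were not called.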

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

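The tests of transcript length, of the mixture of cell types and of unrelated errors were chosen after the results were seen; that of the pace of differentiation was not. Of 32 groups of 4 libraries compared by library measures 2 had a value far from the rest, and of 137 groups compared by the level of a named gene 12 did, where chance gives about 1 in 20. The total expected count of the DMSO ESCs was 10764870 against 10693056 to 10694438, and that of BPS at EB day 9 was 10330378 against 10774465 to 10816066. In 11 of the 12 gene groups the library apart was DMSO. At EB day 4 its Aqp3 was at 2.96 FPKM against 0.94 to 1.05. At EB day 6 Irx1 was at 21.4 against 10.5 to 10.9 and Tnnt1 at 11.5 against 4.73 to 5.36, and at EB day 9 Samd3 was at 1.88 against 5.91 to 6.71. At EB day 12 Otx1 was at 49 against 20.6 to 23.7, Scrt1 at 26.5 against 15.3 to 17.1, Scrt2 at 28.4 against 15.8 to 16.9 and Neurog1 at 26.4 against 14.7 to 16. At EB day 20 Clec3b was at 7.4 against 20.4 to 23, Serpina3m at 26.6 against 7.34 to 9.79 and Serpina3n at 463 against 151 to 202. The other group was Rgl3 at EB day 4, at 20.2 with BPF against 18.4 to 18.5. The response to bisphenols differed between branches at 1326 genes, though RA EB and NPC effects were uncorrelated.

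The first pattern is the distance of bisphenol EBs from DMSO EBs at days 6 to 20. Matrix genes were higher from day 9 (median -0.04 at day 6), smooth muscle genes at days 12 and 20 (medians of -0.50 at day 6 and 0.34 at day 9), and neural progenitor genes were lower at day 9. At days 6 and 12 their fall was lost with an estimated correlation (adjusted p = 0.18 and 0.058), and at day 20 their median was -0.11. Removing length and GC trends left 3252 genes called at EB day 12 against 2951, which argues against such trends. The bisphenol effect correlated across genes with the DMSO change around EB days 6, 9 and 12 at -0.01, -0.32 and 0.06, which argues against a uniformly faster course. At EB day 20 median changes of matrix and endoderm genes differed by 2.53 (permutation p = 1e-05, the smallest possible, ignoring correlation between genes). That argues against fewer neural cells with every other type raised alike. At EB days 9 and 12 these medians were closer (0.72 and 0.51, and 2.37 and 1.83), while lists of other non-neural cells ran from -0.29 for skeletal muscle to 2.40 for endothelium at day 9 and from -0.16 for skeletal muscle to 4.14 for heart (3.88 with 2 members at their bound) at day 12. Differences at these days were not tested. Of the 64 ways to take 1 library of EB days 9, 12 and 20 as the lone one, 1, that with DMSO, had a lowest correlation between stages as high as 0.26 (highest other 0.18), which argues against errors unrelated between these 3 stages, though the test replaced an earlier bound after the correlations were seen. EB day 6 was not in this test, and its effect correlated with theirs at 0.19, 0.12 and 0.11. With 1 DMSO library per stage, a DMSO culture that differed for reasons other than the compounds cannot be told apart from an effect of the compounds.

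The second pattern is the lower level of long transcripts with bisphenols at EB day 4, where the genes called lower had a median length of 11306 bases against 2831 for all. The DMSO library there followed length with a Spearman correlation of 0.44 and the BPA library with -0.42. Removing the trends left 17 of 88 genes, and the median change of those called lower went from -0.66 (SD 0.27) to -0.32 (SD 0.33), so the calls ended because the changes shrank. Length and GC trends were removed together, so a trend over either, or both, is a candidate explanation for most of these calls. Neither was tested alone, and no biological explanation was tested.

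The third pattern is the lower level of collagen and other genes of non-neural cells in bisphenol NPCs. Removing length and GC trends left 34 matrix genes lower against 32, which argues against such trends. More non-neural cells in the DMSO culture could explain medians below 0 in 9 of 10 lists of non-neural cells. In 7 the permutation p = 0.0001, the smallest possible, ignoring correlation between genes. The medians of blood and cardiac genes were -0.10 and -0.02 (permutation p = 0.19 and 0.64), and the highest of the 10 was 0, for liver and gut genes. This and an effect of the compounds stay open.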

How the results depend on the processing

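The fit without DMSO and the removal of length and GC trends were chosen after seeing the data, and the other alternatives before. Of 735 results for genes chosen by the naming rule under 7492 alternatives, 6825 kept direction and side of the threshold, 635 fell short of it, 32 newly passed it and 0 reversed. DESeq2 size factors shifted the median of all genes by at most 0.067. With limma on log2(FPKM + 1) the counts were 11 for bisphenols over stages, 0 for BPA, BPF and BPS, and 0 between BPA and BPS. Between stages limma gave 2385, 1272, 916, 606 and 2627 genes for the steps from ESCs to EB day 20, 3187 for RA EBs, 3490 for NPCs, and 1288 and 3814 for the branches at like age. For bisphenols it gave 1 gene in ESCs and 566 in RA EBs. DESeq2 gave 13 genes for BPA, 90 for BPF, 0 between BPA and BPS and 158 at EB day 4. A filter of 5 CPM gave 96 for BPF, 101 for BPS and 0 between BPA and BPS. The 6 stages after EB day 4 gave 336 for BPS and 2 between BPA and BPS. Without DMSO 4, 146 and 1 genes differed between BPA and BPF, BPA and BPS, and BPF and BPS. With trends removed EB day 4 had 17. Over all comparisons 314 of 899 list tests passed with the preset correlation and 53 with an estimated one. The mean correlation between compounds of 0.75 was 0.16 with the stages divided. The causes of these shifts were not tested.

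Leaving out each stage in turn gave 37 to 1103 genes for bisphenols, 7 to 121 for BPA, 12 to 567 for BPF, 9 to 749 for BPS, 0 to 2 between BPA and BPS and 508 to 1961 for the branches. Leaving out each bisphenol gave 26 to 113 at EB day 4, 107 to 784 at day 6, 504 to 1985 at day 9, 1666 to 3579 at day 12, 1396 to 3912 at day 20, 104 to 451 in RA EBs and 111 to 529 in NPCs. The labels match samples by stage and by treatment only, and the model over stages already holds a term for each. No further pairing was possible. Depth limited genes of few counts, and 1 library per stage and treatment limited single stages. In ESC simulations 63% of log2 changes of 1 were recovered.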

Other observations

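The edgeR exchanges of treatment labels were chosen after results were seen, including those of limma exchanges. Beyond the lists described, surface ectoderm genes in bisphenol EBs of day 12 rose in 13 of 22 and fell in 1 (13 and 1 adjusted over the list alone, median 1.78, or 1.46 with 3 members at their bound, camera adjusted p = 3.8e-10, adjusted p = 0.11 with an estimated correlation), with the epidermal regulator Trp63 at 4.43 ± 0.79, Cdh3 at 3.01 ± 0.55 and the desmosome genes Dsc2 at 2.67 ± 0.53 and Dsp at 2.14 ± 0.41. Endoderm genes rose in 20 of 33 (28 adjusted over the list alone, median 1.83, camera adjusted p = 1e-13, adjusted p = 0.086 with an estimated correlation).

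At EB day 20 skeletal muscle genes rose in 7 of 11 with bisphenols (8 adjusted over the list alone, median 2.08, camera adjusted p = 4.7e-05, adjusted p = 0.086 with an estimated correlation), with the embryonic myosin Myh3 at 4.36 ± 0.72, Myl1 at 4.26 ± 0.89, Myh8 at 3.68 ± 0.57 and Mylpf at 3.64 ± 0.52. Cell cycle genes rose in 14 of 34 (18 adjusted over the list alone, median 0.30, camera adjusted p = 7.5e-11, adjusted p = 0.086 with an estimated correlation), with Rrm2 at 0.69 ± 0.13 and Foxm1 at 0.55 ± 0.11.

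Labels were exchanged between libraries and calls recounted. EdgeR runs with fewer treatment draws came before the 100 given. Between stages, fitted on the libraries compared, mixed splits hold the stage difference as spread, so chance stays open. For the 7 steps, in the order described, 1 of 35 splits gave as many genes, the real one, with 4467, 3089, 2267, 1344, 3903, 5487 and 5546 (highest other 0, 3, 0, 0, 0, 1 and 0), and for the branches at like age 1 of 100, with 2592 and 5931 (highest other 31 and 2457). For treatments, labels were exchanged within stages. Mixed splits again hold the difference as spread, so chance stays open. Within 5 in 100, unadjusted for the 8 treatment results, was bisphenols against DMSO (427 genes, highest other 471, as many in 2 of 100). So was the response by branch (1326, highest other 835, 1 of 100). The 471 had BPA at EB day 4 and BPS in RA EBs in place of DMSO. Above 5 in 100 were BPA (26 genes, highest other 93, 8 of 100), BPF (155, highest other 1200, 13 of 100), BPS (179, highest other 1170, 15 of 100) and BPA against BPS (1, highest other 4, 31 of 100). BPA against BPF and BPF against BPS called 0 genes in edgeR in the real split (336 and 266 at an unadjusted p under 0.05, 0 with limma and DESeq2), and 100 of 100 splits gave as many, with a highest other of 0. The highest count for BPF had EB days 4 to 20 exchanged and that for BPS EB days 6 to 20. The highest count for BPA had NPC day 10 exchanged. Counts several times the real one show that differences from DMSO were not alike at all stages. The reason was not tested. With limma on log2 CPM the real and highest other counts were 22 and 0 for bisphenols, 0 and 3 for BPA, 0 and 623 for BPF, 0 and 581 for BPS and 1328 and 212 for the branches.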
